A study of Mus musculus with 24 samples.

How the data were processed

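Polyadenylated RNA of sorted LSK bone marrow cells from mice of 4 genotypes, given PBS or poly(I:C), was made into 24 libraries in 8 groups, per the labels. The deposited file holds a signal value per gene and library, normalized counts made by the authors per the file name. STAR and the mm10 genome are listed per the submitters' processing notes, and the counter, the normalization tool and the handling of molecular identifiers are not stated. Each column was a whole multiple of its smallest positive value, so whole reads were recovered for 100% of values at a relative tolerance of 1e-06. Depth was 807686 to 8229715 reads per library (median 2583130), and the normalized totals ran from 2.34 to 2.67 M. Of 26267 genes, 16217 had a symbol in the file, 10010 were named from the GRCm38 annotation and 40 stayed unnamed.

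Genes with a normalized count of at least 10 in at least 2 libraries were kept, 12628 in all. Log2 of the normalized count plus 1 was fitted with 8 group means in limma 3.58.1 (R 4.3.3) with a mean-variance trend, and p-values were adjusted with Benjamini-Hochberg at 0.05. The design, the alternatives, the filter and the rule for naming genes were set before the data were examined. Gene lists (32 lists, 1043 members, 1015 of them measured) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, for the 31 lists with at least 5 tested members. Counts of list members were taken over all genes and adjusted over the list alone. The recovered reads were also tested with edgeR 4.0.16 and DESeq2 1.42.0, all 12628 genes in each. Tables were prepared with python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.

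Genes are named by rule: among those with a normalized count of at least 50, the 12 largest changes per direction where at least 5 passed, otherwise those that passed and the 5 smallest p-values, then 4 members of each list and Fancg, Mdm4, Mdm2, Trp53, Cdkn1a and Ly6a. Replicate numbers were checked as pairs. Libraries of one number correlated at a median of 0.343 over 61 pairs (0.0528 to 0.647), against -0.163 for the 189 other pairs, after group means were removed. Comparisons with at least 3 shared numbers that all correlated above 0.1 were treated as paired: FancgKO against WT with PBS (0.218 to 0.528) and with poly(I:C) (0.392 to 0.617), FancgKO_Mdm4Tg against WT (0.248 to 0.389), Mdm4Tg against WT (0.293 to 0.378) and poly(I:C) in WT (0.231 to 0.448). For these a fit with the replicate number as a block is given where it changes a call. Only FancgKO_PBS replicate 4 carries the number 4, so every fit with the block matches that library exactly. It then adds nothing to the blocked FancgKO results.

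The fits were tested on a simulated data set per comparison, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. The changed genes were drawn from those with a mean normalized count of at least 50, so recovery at lower counts was not measured. In FancgKO against WT with PBS, limma recovered 75 genes changed by a log2 of 1 and 100 changed by a log2 of 2, with 0 false calls. With the block it recovered 96 and 100, with 32 false calls. In poly(I:C) against PBS in WT it recovered 71 and 98 with 0 false calls, and with the block 96 and 100 with 4. Without the block it recovered 45 and 94 for poly(I:C) in Mdm4Tg and 55 and 96 for FancgKO against WT with poly(I:C), with 0 false calls. With the block these 2 comparisons had 9 and 5 false calls. Alternatives were other pseudocounts and filters, TMM and quantile scaling, the replicate block, the column-name suffix as a covariate, array weights, no trend, only the compared groups, edgeR, DESeq2 and leaving out each library. Chosen after seeing the data were the averaged contrasts, an Xist covariate, the 18 libraries with low Xist (at most 24.78), thinning of reads to the smallest library, and the block joined with array weights, TMM, edgeR or the Xist covariate, or fitted with FancgKO_PBS replicate 7 left aside.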

Results

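Polyadenylated RNA was sequenced from sorted mouse bone marrow cells that lack lineage markers and carry Sca-1 and Kit (LSK cells), the fraction that holds the blood stem cells and the earliest progenitors. Mice were wild type (WT), lacked Fancg (FancgKO), carried an Mdm4 transgene (Mdm4Tg), or both (FancgKO_Mdm4Tg), and had received PBS or poly(I:C), a synthetic double-stranded RNA that triggers an interferon response and drives stem cells into division. The 24 libraries form 8 groups. With PBS there were 4 WT, 4 FancgKO, 3 FancgKO_Mdm4Tg and 3 Mdm4Tg libraries, and with poly(I:C) there were 3 WT, 3 FancgKO, 2 FancgKO_Mdm4Tg and 2 Mdm4Tg libraries. The depth was 807686 to 8229715 reads per library, with a median of 2583130, and the shallowest group was FancgKO with PBS. The labels give neither dose nor timing of poly(I:C), and no separate animals are stated, so p-values measure only the spread between these samples. All adjusted p-values for genes are from limma with Benjamini-Hochberg adjustment over 12628 genes.

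Mdm4 encodes a partner of p53 that holds this tumour suppressor in check, and its level separated the transgenic libraries from the others. Its normalised count lay between 5023 and 7105 in the 10 libraries with the transgene and between 750.9 and 1293 in the 14 without it. The log2 difference was 2.56 ± 0.14 (SE, n = 3 and 4) for FancgKO_Mdm4Tg against FancgKO with PBS, with a limma adjusted p of 6.09e-11. It was 2.79 ± 0.14 (n = 3 and 4) for FancgKO_Mdm4Tg against WT with PBS at a limma adjusted p of 9.54e-12, and 2.90 ± 0.14 (n = 3 and 4) for Mdm4Tg against WT with PBS at 4.37e-12. With poly(I:C), FancgKO_Mdm4Tg exceeded FancgKO by 2.64 ± 0.16 (n = 2 and 3; limma adjusted p = 1.26e-09). Mdm4 (ENSMUSG00000054387) lies on chromosome 1 at 132959484 to 133030561 of mm10. Whether the pseudogene Mdm4-ps shares reads with it was not tested. Fancg encodes a subunit of the Fanconi anaemia core complex, which starts the repair of DNA crosslinks. Its normalised count was 61.45 to 71.91 in WT libraries with PBS, 68.44 to 78.37 in WT with poly(I:C), 26.13 to 67.06 in FancgKO with PBS, 48.93 to 59.70 in FancgKO with poly(I:C), 39.78 to 71.41 in FancgKO_Mdm4Tg with PBS and 46.73 to 53.30 in FancgKO_Mdm4Tg with poly(I:C). In Mdm4Tg it was 41.25 to 68.01 with PBS and 56.66 to 60.87 with poly(I:C). Fancg (ENSMUSG00000028453, chromosome 4, 43002343 to 43010506) has one total over its exons in the deposited table. Reads outside a deleted part could therefore remain, and the count cannot check the knockout label.

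**Figure D1:**
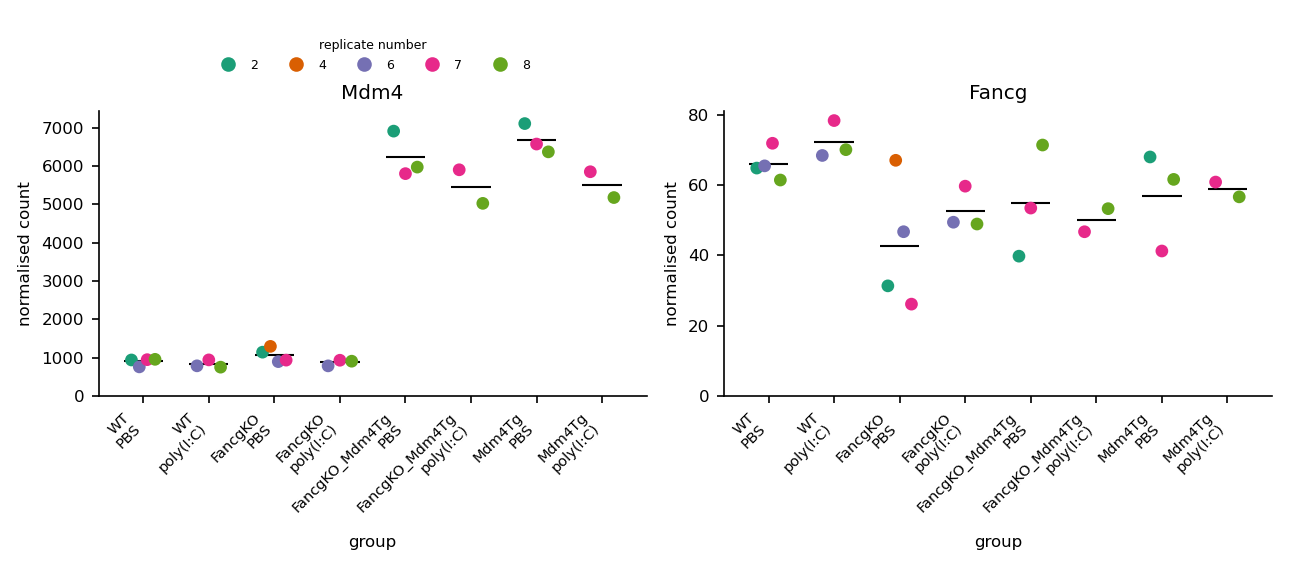
Normalised counts of Mdm4 and Fancg (vertical axes) in each of the 24 libraries, by group, with points coloured by replicate number and lines at group means. Mdm4 sits between 5023 and 7105 in transgenic libraries and at or below 1293 in the rest, while Fancg counts of FancgKO and WT libraries overlap with PBS (26.13 to 67.06 and 61.45 to 71.91) and not with poly(I:C) (48.93 to 59.70 and 68.44 to 78.37).

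The comparison of FancgKO with WT under PBS asks what the loss of the repair complex does to undisturbed stem and progenitor cells. Targets of p53 were higher in FancgKO: 28 of the 40 measured genes of the list were positive, with a median log2 difference of 0.18 (n = 4 and 4; limma's camera test, adjusted p = 3.54e-04, and adjusted p = 0.00678 with an estimated correlation). Within this list the largest values were those of Eda2r, at 2.24 ± 0.50, of the death receptor gene Tnfrsf10b, at 1.62 ± 0.50, and of Pmaip1, which encodes the pro-apoptotic protein Noxa, at 1.61 ± 0.45. These were the 3 p53 targets that passed when adjusted over the list alone, against 0 over all genes (limma adjusted p = 0.477 for Eda2r). Eda2r lies on the X chromosome. Xist was at 7800 and 18007 in FancgKO replicates 6 and 7 with PBS and at most 24.78 in WT, so sex partly coincides with genotype here. With the replicate number as a block, the p53 list had a camera adjusted p of 0.00842, and adjusted p = 0.0595 with an estimated correlation. That block leaves FancgKO_PBS replicate 4 without weight, as no other library carries its number. The cell-cycle inhibitor Cdkn1a, at 0.53 ± 0.41, and Mdm2, the p53 ligase and target, at 0.16 ± 0.12, did not pass (limma adjusted p = 0.999 for both).

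Over all genes, limma called 0 of 12628 between FancgKO and WT with PBS, with 497 at an unadjusted p under 0.05, and edgeR and DESeq2 also called 0. Leaving out FancgKO_PBS replicate 2 gave 1. The fit with the replicate block, which gave 32 false calls on simulated data for this comparison, called 4 genes. That count became 9 without FancgKO_PBS replicate 2, 12 without FancgKO_PBS replicate 6, 1 without WT_PBS replicate 8, and 0 without FancgKO_PBS replicate 7 or WT_PBS replicate 2, 6 or 7. The long noncoding RNA gene Pvt1, a neighbour of Myc, was higher by 1.74 ± 0.27 and Selp, which encodes the adhesion molecule P-selectin, by 1.41 ± 0.25 (limma adjusted p = 0.0223 and 0.0433). Smim8, a small membrane protein gene on chromosome 4, was lower at -2.16 ± 0.36 (limma adjusted p = 0.0223). Without the block the nearest genes that did not pass were Plag1, a zinc-finger transcription factor gene on chromosome 4, at -1.73 ± 0.38, Selp at 1.39 ± 0.33, the tight-junction gene Tjp1 at 1.11 ± 0.30, Ahnak at -0.98 ± 0.27 and Mkl2 at -0.52 ± 0.15. Of the 31 gene lists tested, 11 were called with the preset correlation. Besides the p53 targets these were higher S phase (median 0.10), mitosis (0.12), DNA repair (0.09), myeloid progenitor (0.44), erythroid (0.34), unfolded protein (0.18) and ribosome biogenesis (0.16) lists, and lower lymphoid progenitor (-0.29), stem cell (-0.16) and ribosomal protein (-0.09) lists. For these 10 the smallest was DNA repair at adjusted p = 0.0607 with an estimated correlation, and the others had 0.571 or more. With the replicate block the erythroid list was no longer called (median 0.24, camera adjusted p = 0.0814) and oxidative phosphorylation was (0.12, 0.0058; adjusted p = 0.63 with an estimated correlation), and 10 lymphoid progenitor genes were lower adjusted over the list alone, against 0 without it.

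The Mdm4 transgene was compared on the FancgKO background to ask whether it shifts the knockout, and on WT to see its own effect. Mdm4 itself was the only gene called in FancgKO_Mdm4Tg against FancgKO (n = 3 and 4), in FancgKO_Mdm4Tg against WT (n = 3 and 4) and in Mdm4Tg against WT (n = 3 and 4), all with PBS. In the first of these DESeq2 called 2 genes, and limma called 2 without FancgKO_PBS replicate 2. The p53 target genes did not pass on either background: Cdkn1a was at -0.32 ± 0.44 and Mdm2 at -0.02 ± 0.13 in FancgKO_Mdm4Tg against FancgKO (limma adjusted p = 0.939 and 0.99). As a list they were lower on balance but not called. In FancgKO_Mdm4Tg against FancgKO 28 of 40 were lower (median -0.145, camera adjusted p = 0.101, and 0.639 with an estimated correlation). In Mdm4Tg against WT 25 of 40 were lower (median -0.172, camera adjusted p = 0.116, and 0.54 with an estimated correlation). Against FancgKO the nearest genes that did not pass were Lars2, the mitochondrial leucine ligase, at -1.58 ± 0.41 and Ccdc122 at 1.17 ± 0.31. In FancgKO_Mdm4Tg against WT they were Tjp1 at 1.44 ± 0.32 and Plag1 at -1.55 ± 0.41. In Mdm4Tg against WT they included the histone gene Hist1h4j at -0.79 ± 0.23 and the genes for mitochondrial ribosomal proteins Mrpl4, at -0.85 ± 0.29, and Mrpl16, at -0.71 ± 0.24.

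Among gene lists, FancgKO_Mdm4Tg differed from FancgKO in 5 lists with the preset correlation, opposite in sign to FancgKO against WT where both were called. The myeloid progenitor list was lower in 25 of 27 genes (median -0.53), as were the unfolded protein (-0.24), ribosome biogenesis (-0.20) and replication histone (-0.30) lists, and the lymphoid progenitor list was higher (0.32). All 5 had adjusted p = 0.872 or more with an estimated correlation. Mdm4Tg against WT gave 11 lists, led by lower replication histones (median -0.66, 26 of 26 genes), ribosomal proteins (-0.29, 76 of 78) and oxidative phosphorylation (-0.23, 57 of 61), with adjusted p = 0.54 with an estimated correlation for each. FancgKO_Mdm4Tg against WT gave 1 list, ribosomal proteins at -0.15 (adjusted p = 0.944 with an estimated correlation). With the replicate block Mdm4Tg against WT gave 6 lists, without S phase, mitosis, lymphoid and myeloid progenitor, megakaryocyte and glycolysis genes and with class II antigen presentation (-0.37; adjusted p = 0.803 with an estimated correlation), and 12 replication histone genes were lower adjusted over the list alone, against 0 without it. FancgKO_Mdm4Tg against WT then gave 7, without ribosomal proteins and with higher class I antigen presentation (0.08), S phase (0.07), mitosis (0.09) and ribosome biogenesis (0.12) and lower interferon-stimulated (-0.13), inflammation (-0.21) and lymphoid progenitor (-0.22) lists, the smallest at adjusted p = 0.288 with an estimated correlation. Across genes, FancgKO against WT and FancgKO_Mdm4Tg against FancgKO had r = -0.616 and a covariance of -0.0897. Both use the same FancgKO libraries, and simulated unchanged groups gave r = -0.463 and a covariance of -0.0629. With those libraries split so that neither contrast shared one, r over the 6 splits had a median of -0.06 and ran from -0.165 to 0.241. Genes are not independent replicates, so these r values carry no p.

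Poly(I:C) was compared with PBS within each genotype to see the response of LSK cells and whether genotype alters it. In WT (n = 3 and 4) Trib2, a pseudokinase gene that directs degradation of the myeloid factor C/EBP alpha, rose by 2.35 ± 0.40, and H2-Ob, a subunit of the class II antigen-loading regulator, fell by 1.62 ± 0.28 (limma adjusted p = 0.0488 for both). No other gene passed, with 1881 at an unadjusted p under 0.05, while edgeR called 7 and DESeq2 239. Without WT_PBS replicate 6, limma called 520 genes, and without any other of the 7 libraries (WT_PBS replicate 2, 7 or 8, WT_PolyIC replicate 6, 7 or 8) it called 0. The replicate numbers pair these libraries, and with the replicate block 411 genes were higher and 458 lower, 869 in all. That number was 292 without WT_PBS replicate 8, 272 without WT_PolyIC replicate 7 and 217 without WT_PolyIC replicate 8. With that block granulocyte and monocyte genes were among the largest rises. The monocyte surface gene Ly6c2 rose by 3.14 ± 0.65, the complement gene C3 by 3.00 ± 0.68, the Fc receptor gene Fcgr3 by 2.87 ± 0.52 and Ms4a3 by 2.77 ± 0.52 (limma adjusted p = 0.00591, 0.0109, 0.00292 and 0.00358). Hdc, which makes histamine in mast cells and basophils, rose by 2.31 ± 0.44 (0.00396). Falls with the block included the guidance gene Sema3d at -2.65 ± 0.32 and the lymphocyte GTPase gene Gimap6 at -1.53 ± 0.21 (limma adjusted p = 1.44e-04 and 3.53e-04).

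In WT, 19 lists were called with the preset correlation. Myeloid progenitor genes were higher (median 1.25; 19 of 27 passed adjusted over the list alone, 0 over all genes), as were erythroid genes (1.35; 12 and 0), while lymphoid progenitor genes were lower (-1.07; 10 and 0) and stem cell genes too (-0.63; 17 and 0). With the replicate block 17 myeloid progenitor and 7 erythroid genes were higher over all genes, and 15 lymphoid progenitor and 19 stem cell genes lower. Most other lists gained members with it, such as 11 unfolded protein, 6 oxidative phosphorylation and 5 S phase genes higher over all genes, and 14, 27 and 12 adjusted over the list alone. For these 4 lists limma's camera gave adjusted p = 0.226 with an estimated correlation, and no other list had less. With the replicate block the lymphoid progenitor list had adjusted p = 0.0263 with an estimated correlation. The block also ended the call of replication histones (median 0.08) and added lower inflammation (-0.40) and TGF-beta (-0.22) lists, at adjusted p = 0.102 and 0.244 with an estimated correlation. FancgKO and FancgKO_Mdm4Tg each gave 17 lists and Mdm4Tg 19, with myeloid progenitor medians of 1.01, 1.08 and 1.25 and stem cell medians of -0.56, -0.58 and -0.69. Their smallest values were adjusted p = 0.445, 0.3 and 0.267 with an estimated correlation.

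In the other genotypes limma called 0 genes without the block, with 914 (FancgKO, n = 3 and 4), 1082 (FancgKO_Mdm4Tg, n = 2 and 3) and 1605 (Mdm4Tg, n = 2 and 3) at an unadjusted p under 0.05. Here edgeR called 0, 0 and 13 genes and DESeq2 called 0, 5 and 45. In Mdm4Tg limma called 11 without Mdm4Tg_PBS replicate 7. These comparisons share only 2 replicate numbers each and so were not treated as paired. With the replicate block limma called 0 genes in FancgKO, 136 in FancgKO_Mdm4Tg and 612 in Mdm4Tg. Among the genes nearest to passing without the block was Il1rl1, the receptor for interleukin 33 on mast cells. It was at 2.51 ± 0.46 in Mdm4Tg and 2.15 ± 0.46 in FancgKO_Mdm4Tg, and Trib2 was at 2.47 ± 0.48 in FancgKO_Mdm4Tg. The IgE receptor gene Ms4a2 was at 2.34 ± 0.45 in Mdm4Tg, 2.18 ± 0.45 in FancgKO_Mdm4Tg and 1.44 ± 0.37 in FancgKO (limma adjusted p = 0.0925, 0.282 and 0.682). Across all genes the responses of genotype pairs correlated at r = 0.595 to 0.757. With the replicate block r was 0.51 to 0.722. Genotypes share no libraries here, but they share replicate numbers, and genes are not independent replicates. Of the 869 genes called in WT with the block, 864 had the same sign in Mdm4Tg, 856 in FancgKO_Mdm4Tg and 830 in FancgKO.

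A contrast that averages poly(I:C) against PBS over the 4 genotypes, added after the data were seen, used all 10 poly(I:C) and 14 PBS libraries. It called 1509 genes higher and 1465 lower, 2974 in all, and 1554 without FancgKO_Mdm4Tg_PolyIC replicate 8. Granulocyte and monocyte genes were among the largest rises. Elane, which encodes neutrophil elastase, rose by 3.06 ± 0.58, Ly6c2 by 3.05 ± 0.49, Fcgr3 by 2.89 ± 0.46, the haptoglobin gene Hp by 2.88 ± 0.63 and Ms4a3 by 2.85 ± 0.43 (limma adjusted p from 5.39e-04 to 0.00332). The erythroid carbonic anhydrase gene Car1 rose by 2.47 ± 0.42, the mast cell genes Hdc by 2.22 ± 0.36 and Ms4a2 by 1.92 ± 0.20, and the chemokine receptor gene Ccr2 of monocytes by 1.95 ± 0.31 (limma adjusted p = 7.47e-04, 6.37e-04, 1.79e-05 and 6.07e-04). Mecom, a transcription factor gene that maintains long-term stem cells, fell by 1.30 ± 0.23. Among lymphoid genes, Dntt, the terminal transferase of early lymphocytes, fell by 1.71 ± 0.38, the cytokine receptor gene Flt3 by 1.11 ± 0.17 and the chromatin organiser gene Satb1 by 1.01 ± 0.16. The largest falls were in Sema3d, at -2.35 ± 0.45, Usp43, at -2.22 ± 0.41, and CT010467.1, at -2.18 ± 0.37 (limma adjusted p = 0.0014, 0.00105 and 7.13e-04). CT010467.1 is a ribosomal RNA gene with counts of 7978 to 157700 in PBS libraries and 4555 to 22430 in poly(I:C) libraries, and whether its fall reflects library quality was not tested. Smaller rises included those of the cell-cycle genes E2f8, by 0.69 ± 0.08, and Ccne1, by 0.98 ± 0.19, and of the endoplasmic reticulum chaperone gene Calr, by 0.87 ± 0.16. Ly6a, which encodes the Sca-1 antigen of the sort gate, was at -0.20 ± 0.22 and did not pass (limma adjusted p = 0.518). Its normalised counts were only 11.69 to 45.91, under the floor of 50 for named genes, so a change in Ly6a could be missed.

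**Figure D2:**
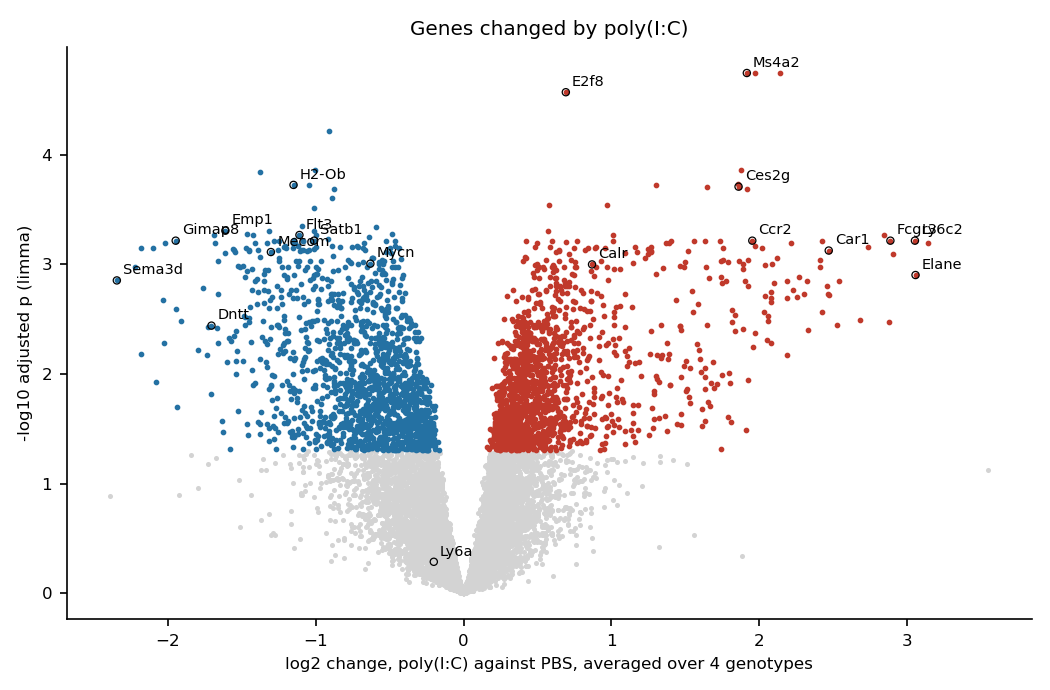
Log2 change (horizontal axis) and -log10 limma adjusted p (vertical axis) of 12628 genes for poly(I:C) against PBS averaged over 4 genotypes. Red and blue points are the 1509 genes higher and the 1465 lower, grey points did not pass, and circled genes are named.

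In the averaged contrast the myeloid progenitor list had 23 genes higher and 1 lower of 27 over all genes (median 1.06), 24 and 1 adjusted over the list alone. The erythroid list had 20 higher of 29 (median 1.10; 21 adjusted over the list alone), mast cell and basophil genes 4 of 7 (0.86), monocyte and macrophage genes 6 of 11 (0.80) and megakaryocyte genes 9 of 24 (0.50). The stem cell list had 27 genes lower and 1 higher of 42 (median -0.62; 28 lower adjusted over the list alone), the lymphoid progenitor list 14 lower of 28 (-0.86; 20 lower adjusted over the list alone) and B cell genes 2 lower of 7 (-0.98). Further lists were higher on balance, with the genes that passed in brackets: oxidative phosphorylation (51 of 61 genes, median 0.49), mitochondrially encoded genes (4 of 9, 0.50), unfolded protein (13 of 21, 0.56), replication histones (7 of 26, 0.49), ribosomal proteins (26 of 78, 0.35), ribosome biogenesis (15 of 31, 0.31), glycolysis (5 of 23, 0.26), S phase (18 of 48, 0.23) and mitosis (17 of 52, 0.19). Class I antigen presentation was higher (7 of 22, median 0.265), while interferon-stimulated genes were lower on balance, with 14 lower and 6 higher of 56 (median -0.15). Camera called these 19 lists with the preset correlation, and none held, the smallest at adjusted p = 0.223 with an estimated correlation. The share of counts from the mitochondrial chromosome, mostly ribosomal RNA, was 9.41% to 10.62% in the poly(I:C) libraries numbered 8. It was 5.27% to 7.67% in the other poly(I:C) libraries and 5.33% to 8.28% with PBS, so a high share was confined to 1 replicate number.

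Among the 56 interferon-stimulated genes, Slfn8 fell by 0.53 ± 0.08, Ifi203 by 0.69 ± 0.14 and Slfn5 by 0.82 ± 0.18, and Ly6e rose by 0.68 ± 0.13 (limma adjusted p from 6.07e-04 to 0.00392). Fry, which asks whether a list moves one way on balance and, as a mixed test, whether its members change in either direction, called 19 and 25 lists and compares no list with other genes. Camera did not call the remaining lists: p53 targets (median 0.04, with 8 higher and 5 lower of 40), class II antigen presentation (-0.29), inflammation (-0.26), cytokine feedback (-0.003), T and natural killer cells (-0.10), dendritic cells (0.23), endothelial and stromal cells (-0.05), the Fanconi pathway (0.04), DNA repair (-0.01), TGF-beta (-0.21), apoptosis (0.06) and immediate early genes (0.24). Mature neutrophil genes had 4 measured members, too few to test (median 0.765).

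**Figure D3:**
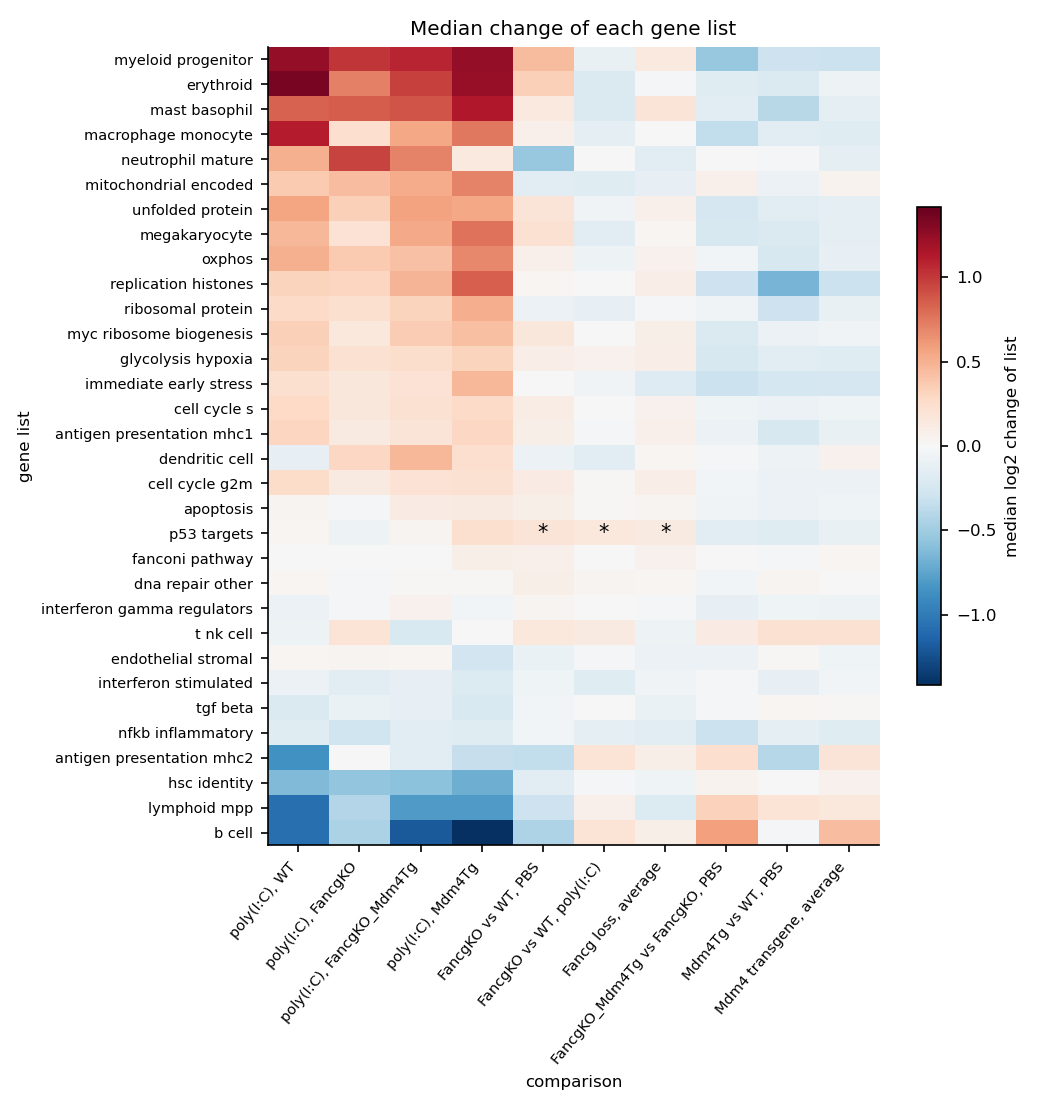
Median log2 change (colour) of each of 32 gene lists (vertical axis) in 10 comparisons (horizontal axis). Stars mark lists with a camera adjusted p under 0.05 with an estimated correlation, which are the p53 targets in the 3 contrasts for Fancg loss.

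Under poly(I:C), FancgKO against WT (n = 3 and 3) had 0 genes called by limma, edgeR and DESeq2, with 46 at an unadjusted p under 0.05 in limma. The p53 target list was again higher, with 30 of 40 genes positive and a median of 0.15 (camera adjusted p = 0.00338, and adjusted p = 0.0195 with an estimated correlation). Its leading members were Phlda3, an Akt inhibitor gene, at 1.42 ± 0.77 and the DNA polymerase gene Polk at 0.35 ± 0.22, and 0 of them passed over all genes or adjusted over the list alone. Interferon-stimulated genes were lower in 47 of 56 cases (median -0.17, camera adjusted p = 5.02e-09, and adjusted p = 0.0834 with an estimated correlation), among them Usp18, a brake on interferon signalling, at -0.81 ± 0.34 and Ifitm3 at -0.35 ± 0.20. The other lists called were erythroid (-0.21), megakaryocyte (-0.16) and ribosomal protein (-0.12), each with adjusted p = 0.962 with an estimated correlation. The replicate block added class II antigen presentation (0.19), inflammation (-0.12) and mitochondrially encoded (-0.17) lists, 8 in all, at adjusted p = 0.61, 0.141 and 0.771 with an estimated correlation. FancgKO_Mdm4Tg against FancgKO under poly(I:C) (n = 2 and 3) gave Mdm4 alone and 0 lists, and the next genes were Slc35a1 at 0.60 ± 0.22 and Lcmt1 at -0.66 ± 0.27.

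Whether genotype alters the response was tested as a difference of differences. For poly(I:C) in FancgKO minus that in WT, limma called 0 genes, with 128 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. The nearest genes were Grb10, an adaptor that restrains insulin signalling, at -1.21 ± 0.35 and Fam222b at 1.10 ± 0.36 (n = 3, 4, 3 and 4). The myeloid progenitor list had a smaller rise in FancgKO (median difference -0.51, 22 of 27 genes) and the lymphoid progenitor list a smaller fall (0.41, 24 of 28 genes; camera adjusted p = 3.88e-04 for both, and adjusted p = 0.713 with an estimated correlation). For FancgKO_Mdm4Tg minus FancgKO, and for the transgene's effect with PBS on FancgKO minus on WT, limma called 0 genes, with 102 and 265 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. The first gave higher myeloid progenitor (0.39) and ribosome biogenesis (0.17) lists, both with adjusted p = 0.984 with an estimated correlation. The second gave higher ribosomal protein (0.23), oxidative phosphorylation (0.15) and replication histone (0.39) lists, each with adjusted p = 0.988 with an estimated correlation. Nearest were Lins1 at 1.13 ± 0.38 in the first and Naxe, a metabolite repair enzyme gene, at 1.37 ± 0.34 in the second.

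**Figure D4:**
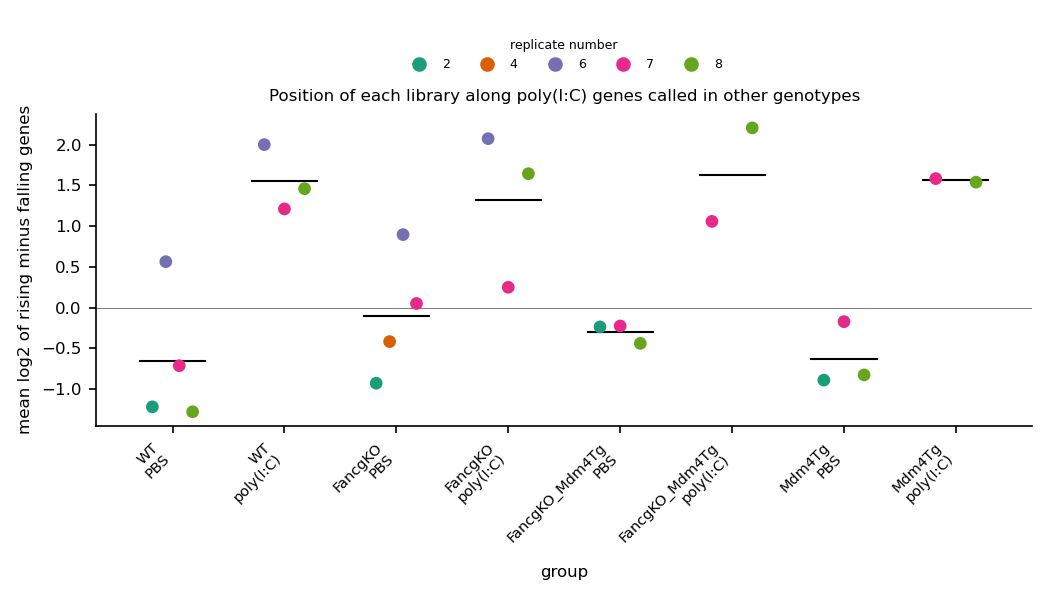
Mean log2 level of genes that rise minus genes that fall with poly(I:C) (vertical axis) in each library, by group, over genes called in the other genotypes. Group means are -0.661 and 1.56 in WT and -0.0997 and 1.32 in FancgKO, with PBS and with poly(I:C).

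Averaged over transgene and treatment, a contrast also added after the data were seen, Fancg loss (12 against 12 libraries) gave 2 genes. Tjp1 rose by 1.22 ± 0.18 and Plag1 fell by 1.67 ± 0.22 (limma adjusted p = 0.00373 and 0.00223), with 267 genes at an unadjusted p under 0.05, 3 called by edgeR, 7 by DESeq2, and 4 by limma without WT_PBS replicate 6. Limma called 0 in the 18 libraries with low Xist, 1 with reads thinned to the smallest library and 14 with the replicate block. Plag1 lies on chromosome 4, as Fancg does, and whether this position bears on its fall was not tested. The p53 target list was higher in 33 of 40 genes, with a median of 0.125 (camera adjusted p = 5.14e-08, and adjusted p = 9.69e-05 with an estimated correlation). Eda2r, at 1.59 ± 0.30, and Zmat3, a p53-induced RNA-binding protein gene, at 0.71 ± 0.20, passed adjusted over the list alone, against 0 over all genes (limma adjusted p = 0.0986 and 1.0). Fancg loss gave 13 further lists, led by higher mitosis genes (median 0.09, 49 of 52) and lower lymphoid progenitor genes (-0.20, 26 of 28), the smallest at adjusted p = 0.16 with an estimated correlation. Without the replicate block, the p53 list in these 3 contrasts for Fancg loss was the only list call that held with an estimated correlation. Averaged in the same way, the transgene (10 against 14 libraries) gave Mdm4 alone, at 2.71 ± 0.08 (limma adjusted p = 4.68e-17), or 2 genes without FancgKO_PBS replicate 4 and 3 with DESeq2. The p53 list was then lower in 28 of 40 genes (median -0.10, camera adjusted p = 0.0167, and adjusted p = 0.17 with an estimated correlation), along with 13 others of which the smallest had adjusted p = 0.513 with an estimated correlation. Eda2r was at -0.56 ± 0.30 and Bbc3, which encodes the pro-apoptotic protein Puma, at -0.50 ± 0.22.

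**Figure D5:**
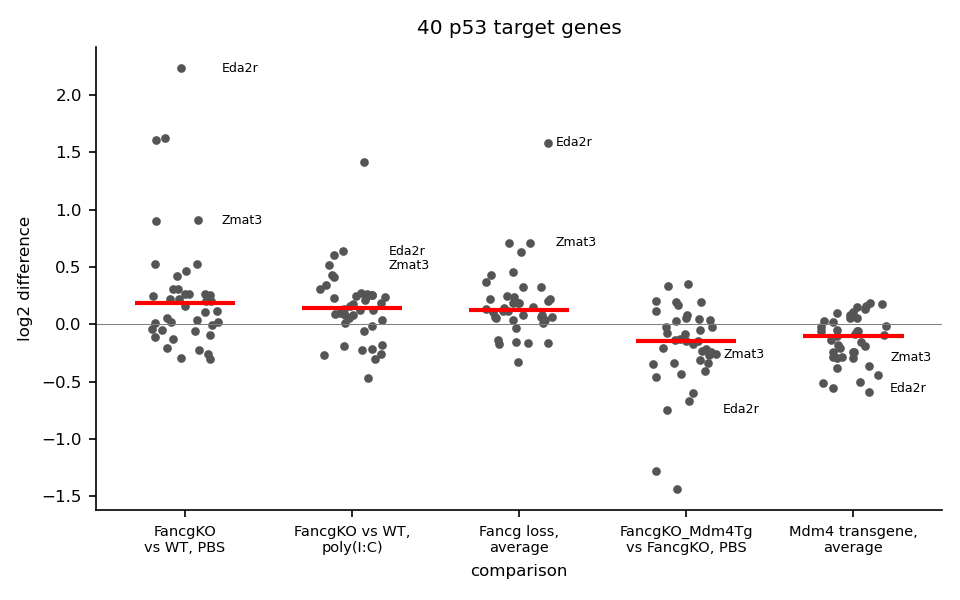
Log2 differences (vertical axis) of the 40 measured p53 target genes in 5 comparisons (horizontal axis). Points are genes and red lines are medians, at 0.18, 0.15 and 0.125 for Fancg loss. They are at -0.145 for FancgKO_Mdm4Tg against FancgKO with PBS and at -0.10 for the transgene averaged over genotype and treatment.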

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

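In WT with PBS, replicate 6 lay far from the other 3 libraries in 2 measures. Its Elane count was 682, against 13.4 to 97 in the others, and its Mdm4 count was 758, against 938 to 955. Of 74 groups of values tested 2 lay outside, and chance flags about 1 in 20 groups, or 3.7 here. That count does not show that replicate 6 differs by chance alone. Its mean level of genes that rise minus genes that fall with poly(I:C) was 0.563. It was 0.895 in FancgKO_PBS replicate 6 and -1.278 to 0.05 in the other WT and FancgKO libraries with PBS. Without WT_PBS replicate 6, limma called 520 genes for poly(I:C) in WT, against 2 with it. What sets the libraries numbered 6 apart was not tested.

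Several gene lists met the rule for a difference between groups by a test of the difference itself (camera with the preset correlation), and none of them held, the smallest at adjusted p = 0.713 with an estimated correlation. For the poly(I:C) response in FancgKO minus WT the median differences were 0.48 for class II antigen presentation, 0.409 for lymphoid progenitors, -0.511 for myeloid progenitors, -0.469 for erythroid, -0.364 for megakaryocyte, -0.228 for unfolded protein, -0.195 for ribosome biogenesis, -0.114 for oxidative phosphorylation, -0.112 for S phase and -0.0942 for mitosis genes. For the response in FancgKO_Mdm4Tg minus FancgKO they were 0.387 for myeloid progenitors and 0.173 for ribosome biogenesis. For the effect of the transgene on FancgKO minus on WT they were 0.228 for ribosomal proteins, 0.149 for oxidative phosphorylation and 0.39 for replication histones.

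The test of the 2 FancgKO libraries numbered 7 was written before its result was seen, and the test of the PBS libraries after. The smaller poly(I:C) response in FancgKO had a median ratio of 0.466 to the Mdm4Tg response over 612 genes. Without the 2 FancgKO libraries numbered 7 the ratio was 0.683, against 0.745 for WT, and whether these libraries account for the difference cannot be told apart from an effect of genotype. Whether FancgKO PBS libraries were already shifted toward the poly(I:C) state cannot be told apart from a smaller response: 70.5% of the gap in the mean score lies in the PBS libraries (47.9% to 216% with each library left out), where FancgKO exceeds WT by 0.562 (exact permutation p = 0.343, pairs ignored). The 3 shared numbers all differ in that direction, with -0.928 against -1.218 for number 2, 0.895 against 0.563 for 6 and 0.05 against -0.713 for 7, too few pairs for an exact p under 0.05. The difference of differences called 0 genes.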

How the results depend on the processing

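No named gene passed the threshold in the opposite direction under any alternative, and the Mdm4 and Fancg values all stayed on their side of the threshold. Of the gene values, 3856 of 3892 for poly(I:C) averaged over genotypes were the same, 35 weaker and 1 stronger. In poly(I:C) for WT 525 of 804 were the same, 26 weaker and 253 stronger. Counts that moved by over 1.5 times follow by setting, and the cause was not tested unless the setting itself tests fewer reads or libraries. The replicate block changed FancgKO against WT with PBS to 4, poly(I:C) in WT to 869, in FancgKO_Mdm4Tg to 136 and in Mdm4Tg to 612, averaged Fancg loss to 14, the averaged transgene to 2 and the overlap of poly(I:C) genes of WT and Mdm4Tg to 366 (expected 9.37 higher and 11.8 lower), and in the paired comparisons, beyond the list calls given beside their results, it changed no other call of a whole list. Averaged poly(I:C) went to 3903 with the block, with 2697 of the 2974 genes called in both, and 17 of 24 libraries correlated best with one of their own number. For averaged Fancg loss the block brought Eda2r past the threshold over all genes (1.57, limma adjusted p = 0.0198). Some list medians changed sign with the block, such as immediate early genes for poly(I:C) in WT (0.226 to -0.199) and myeloid progenitors for FancgKO_Mdm4Tg against FancgKO with poly(I:C) (-0.146 to 0.172). In the order FancgKO against WT with PBS, poly(I:C) in WT, FancgKO_Mdm4Tg and Mdm4Tg, Fancg loss and the transgene, the block with TMM gave 4, 888, 136, 620, 14 and 2. The block with array weights gave 9, 1526, 281, 2385, 29 and 2, with 1627 for poly(I:C) in FancgKO, 1 for FancgKO against WT with poly(I:C) and 5301 for averaged poly(I:C). EdgeR with the block gave 1, 1652, 311, 1576, 16 and 3, with 2 for poly(I:C) in FancgKO, 1 for the difference of responses between FancgKO and WT and 5023 for averaged poly(I:C). The block with FancgKO_PBS library 7 left aside gave 2 for FancgKO_Mdm4Tg against FancgKO, 1198, 1, 227 and 1105 for poly(I:C) in WT, FancgKO, FancgKO_Mdm4Tg and Mdm4Tg, 4472 averaged, 13 for Fancg loss and 2 for the transgene. The block with an Xist covariate gave 364, 57 and 385 for WT, FancgKO_Mdm4Tg and Mdm4Tg, and 14 for Fancg loss. The suffix covariate gave 1 for FancgKO against WT, 350 and 10 for poly(I:C) in WT and Mdm4Tg, and 8 for Fancg loss. Array weights gave 1659 and 597 for poly(I:C) in WT and Mdm4Tg and 4860 averaged. Poly(I:C) in WT had 0 genes with a pseudocount of 0.5, no filter, quantile scaling, no trend, an Xist covariate or the 18 libraries with low Xist, 9 with a pseudocount of 5, 7 with edgeR, 239 with DESeq2 and 1 with thinned reads. Other moves were, for Mdm4Tg, 23 with only the compared groups, 13 with edgeR and 45 with DESeq2; for DESeq2, 2 in FancgKO_Mdm4Tg against FancgKO, 5 for poly(I:C) in FancgKO_Mdm4Tg, 7 for Fancg loss and 3 for the transgene. Without a filter there were 2 for Mdm4Tg against WT, 2 for poly(I:C) in FancgKO, 4 for Fancg loss and 3 for the transgene, which had 2 with a pseudocount of 5. Fancg loss had 4 with an Xist covariate, 0 in the 18 libraries and 1 with thinned reads, where averaged poly(I:C) had 1787. The opposition of contrasts went from -0.616 to -0.0572 with split libraries. Without the block, an estimated correlation left 1 list in each contrast for Fancg loss and 0 elsewhere, and with it 0 for FancgKO against WT with PBS, 1 with poly(I:C), 3 for averaged Fancg loss, 1 for poly(I:C) in WT and 0 elsewhere. Without the block, fry called 2 for FancgKO against WT with PBS, 2 for poly(I:C) in WT, 1 for averaged Fancg loss, 19 for averaged poly(I:C) and 0 elsewhere. With the block it called 3, 13, 3 and 21 for these, 1, 6 and 15 for poly(I:C) in FancgKO, FancgKO_Mdm4Tg and Mdm4Tg, and 0 elsewhere. Lists with the block numbered 2 for FancgKO_Mdm4Tg against FancgKO, 7 against WT, 6 for Mdm4Tg, 8 for FancgKO against WT with poly(I:C), 6 for FancgKO_Mdm4Tg against FancgKO with poly(I:C), 6 for the difference of their responses and 5 for the averaged transgene.

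Leaving out each library gave 0 to 1 genes in FancgKO against WT with PBS (block 0 to 12), 1 to 2 in FancgKO_Mdm4Tg against FancgKO, 0 to 520 for poly(I:C) in WT (block 217 to 766), 0 to 11 in Mdm4Tg, 1554 to 3584 averaged, 2 to 4 for Fancg loss and 1 to 2 for the transgene, and the other counts stayed the same. Where 1 library is left in a group, it is assumed to vary like the other groups. With 807686 reads in the smallest library, changes in genes of low count are out of reach.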

Other observations

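Xist, expressed from the inactive X chromosome of females, had normalized counts of 5943 and 20207 in WT_PolyIC replicates 6 and 7, 7800 and 18007 in FancgKO_PBS replicates 6 and 7, and 13767 and 363 in FancgKO_PolyIC replicates 6 and 7, with the other libraries at most 24.78. High Xist thus partly coincides with genotype in FancgKO against WT with PBS, and with treatment in poly(I:C) against PBS in WT. The Y-linked gene Ddx3y, chosen after its values were seen, was found beside Xist in FancgKO_PBS replicate 6 (219), WT_PolyIC replicate 6 (223) and FancgKO_PolyIC replicate 7 (365), so a library is not shown to come from 1 animal. Slc30a7, a zinc transporter gene chosen after its values were seen, reached 33139 and 12737 in FancgKO_PBS replicates 4 and 7, 15579 in FancgKO_Mdm4Tg_PBS replicate 2, 8573 in Mdm4Tg_PBS replicate 8 and 3856 and 5124 in WT_PBS replicates 6 and 7. It was 1813 to 2537 in replicate 8 of WT, FancgKO and FancgKO_Mdm4Tg with poly(I:C), and 199.3 to 307.74 in the other libraries. Of 104 tested genes within 10 Mb of Fancg, 6 had a limma p under 0.05 for averaged Fancg loss against 2.17 expected (1-sided exact Fisher p = 0.0229), and 11 against 6.37 with the replicate block, a test chosen after the results were seen. Of the 14 genes called for averaged Fancg loss with the block, 3 lie on the chromosome of Fancg, which holds 5.73% of tested genes. These are Plag1, starting at 3900996, Smim8 at 34768664 and Zfp992 at 146449023, and only Smim8 is within 10 Mb of Fancg.

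Group labels were also exchanged among libraries, each count below including the real arrangement. As many genes were called in 35 of 35 splits for FancgKO against WT with PBS (real 0, highest other 1974), 6 of 35 for FancgKO_Mdm4Tg against FancgKO (1, 40), 1 of 35 for FancgKO_Mdm4Tg against WT (1, 0), 2 of 35 for Mdm4Tg against WT (1, 4), 2 of 35 for poly(I:C) in WT (2, 690) and 35 of 35 in FancgKO (0, 138). They were 100 of 100 for the difference of responses between FancgKO and WT (0, 963) and for that of transgene effects (0, 1695), 1 of 100 for averaged poly(I:C) (2974, 2009), 4 of 100 for Fancg loss (2, 276) and 5 of 100 for the transgene (1, 3097). Splits that call many more genes than the real arrangement point to a structure of the samples other than the labels. For FancgKO against WT with poly(I:C) the 10 splits are too few for a share under 0.05 (real 0, highest other 0, as many in 10). So are the 8 splits with the block that part all 3 pairs, for poly(I:C) in WT (869, 9, as many in 1) and FancgKO against WT with PBS (4, 0, as many in 1). Splits with the block that part 2 of the 3 pairs called up to 228 genes in the former and up to 8 in the latter.

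As many lists were called in 16 of 35 splits for FancgKO against WT with PBS (real 11, highest other 19), 25 for FancgKO_Mdm4Tg against FancgKO (5, 17), 34 for FancgKO_Mdm4Tg against WT (1, 17), 17 for Mdm4Tg against WT (11, 17), 2 for poly(I:C) in WT (19, 20) and 5 in FancgKO (17, 18). They were 9 of 10 for FancgKO against WT with poly(I:C) (5, 15), 56 of 100 for the difference of responses (10, 19), 89 for that of transgene effects (3, 18), 5 for averaged poly(I:C) (19, 19), 9 for Fancg loss (14, 20) and 21 for the transgene (14, 18). Mdm4 was as far apart only in the real arrangement, 1 of 35 in each PBS contrast (2.56, 2.79 and 2.90, highest others 2.09, 2.15 and 2.23) and 1 of 100 averaged (2.71, highest other 1.97).

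For the poly(I:C) shift the sex test was written before its result was seen, and the depth and sort gate tests after. The averaged contrast called 2974 genes. Depth as the whole cause is argued against. After every library was thinned to the smallest, 1787 genes were called, among them 1606 of the 2974. Of the 2593 of them still tested, 2592 kept their sign. The remaining calls were lost, so how much of the shift depends on depth stays open. A mix of sexes is argued against too, with 99.8% of 434 genes called over WT and FancgKO of the same sign in transgenic libraries, whose Xist counts are at most 3.93. Progenitor cells entering the sort gate stay open: 4 of 4 progenitor lists had a positive median, which this explanation and a change within stem cells both predict.

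For the p53 target list with Fancg loss the tests of sex, X-linked genes and depth were written before their results were seen. The list had the smallest camera p only in the real arrangement, 1 of 35 splits with PBS (median 0.182, highest other 0.209) and 1 of 100 averaged (0.125, highest other 0.12), while 10 splits with poly(I:C) are too few (0.146, highest other 0.117, as small in 1). The 35 splits with PBS ignored the pairs by replicate number, and only 8 of them part all 3 pairs. A mix of sexes is argued against by a camera p of 6.77e-05 in transgenic libraries, with Xist at most 3.93 (limma, median 0.107). Leaving out X-linked members kept 39 of the 40 genes, so the list hardly changed, and the camera p was 1.23e-07. This shows only that the shift does not rest on X-linked members. With thinned reads the camera p was 0.00536, which argues against depth as the whole cause, but the median over 29 genes was 0.0431, so how much of the shift depends on depth stays open. Open too is whether more p53 activity or a different mix of cells raises the list, which these tests do not separate.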
